A study of Homo sapiens with 4 samples.

How the data were processed

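RNA was measured by sequencing in 4 libraries of LM2 cells, a lung metastatic derivative of MDA-MB-231, which is a mesenchymal line from a human breast cancer. The titles assign 2 libraries to hnRNPM knockdown and 2 to control, each numbered 1 and 2, and cells were collected 48 h after plating. The labels name the silencing agent in 2 ways: the growth protocol speaks of cells expressing an shRNA, and the treatment label and the design text speak of an siRNA. Its sequence is not given in the sources used here, so "knockdown" is used throughout. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

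The authors deposited 1 table of RPKM values (reads scaled by transcript length and by a read total) for 36525 Ensembl genes, with 1 column per library. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7 to the human build hg19; the counting program, its use of strand and its handling of reads with several matches are not given in the sources used here. No column of per-sample values was left unused (0 columns). Of the gene IDs, 32172 were named from a current symbol table, 136 from GENCODE 29 and 4217 had no name. The reference annotation was of another build, so no coordinates are given, and it was used for names, gene types, exon lengths, 3′ UTR sequences and overlaps between genes. The table held 0 genes from each of the chromosomes 20, 21 and 22, and these chromosomes were not analysed here. Members of gene lists or families that lie on them could therefore not be tested.

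RPKM values are not counts, so depth was first sought in their steps. Among low values, 1 read was worth the same in both libraries of a group and 1.41 times as much in the knockdown as in the control libraries. With GENCODE 29 exon lengths, the steps corresponded to read totals of 41.9 M for both control and 29.7 M for both knockdown libraries, at which 59.8% of 13594 genes lay, and 82.9% of 29128 low values were then whole reads within 0.1 read. These steps point to a read total shared by both libraries of a group, so the deposited RPKM values may not be scaled to each library's own depth. The RPKM sums were 162466 and 187293 in the control and 163078 and 180958 in the knockdown libraries. Reads estimated in this way summed to 23.0 M and 26.6 M in the control and 16.5 M and 18.3 M in the knockdown libraries. These estimates were used for depth and for checks, never for a count test.

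Libraries of 1 group differed by little more than counting error. With the depth ratio taken out, the mean chi-square per gene was 1.35 over 14747 genes between the control libraries and 1.34 over 13848 genes between the knockdown libraries, where counting error alone gives about 1. Between libraries of different groups it was 91.2 to 101. The libraries of a group were kept as 2 samples.

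Values were analysed as log2(RPKM + 0.5) for the 13627 genes with a mean RPKM of at least 1, with limma 3.58.1 in R 4.3.3 (a linear model on group alone, empirical Bayes with a variance trend, Benjamini-Hochberg adjustment, threshold 0.05). A log2 fold change is the knockdown mean minus the control mean on this scale, which understates the change of low genes. Plain ratios are ratios of mean RPKM. Errors of means are SD (n = 2) and errors of log2 fold changes are standard errors (SE). limma estimated no spread of the variance between genes beyond its trend, so all genes were tested against a shared variance, and very small p-values rest on that. With median-ratio scaling the median SE fell from 0.175 to 0.054. Much of the spread in the main fit was thus shared by the genes of a library, as a depth difference would be. The SDs of RPKM hold it too, and genes that did not pass failed against it. An exact permutation test of 2 against 2 libraries has 3 splits and cannot go below a two-sided p of 0.333, so none was run. Gene sets with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, then with an estimated correlation and with fry. The estimated correlation draws on differences between libraries of a group, and a depth difference shared by all genes enters it. With it, camera gave every list an adjusted p of 0.994, so it cannot tell lists apart. Neither this form of camera nor fry was run on rescaled values, and fry also draws on differences between libraries of a group.

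Before the data were examined, 25 gene lists, the tests, the alternatives and a rule for named genes were fixed. The rule takes HNRNPM, CD44, CDH1, CDH2, VIM, FN1, ESRP1, ESRP2, SNAI2, ZEB1 and PTBP1 whatever their result. It adds the 12 largest and 12 smallest log2 fold changes among genes past the threshold whose groups do not overlap, and up to 4 members per list with the smallest p. It gave 120 genes. Other names were chosen after their values were seen: MUC1, CDH3, ERBB3, EHF, CLDN7, SPINT2, EPCAM, KRT19, ID3, INHBA, NEDD9, ADAM17, MCM7, TYMS, CENPE, NUPR1, GAPDH, RPL27A and all collagen, mitochondrial and 3′ UTR site genes of the closing section.

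The lists were the hnRNP family, SR proteins and other splicing regulators, genes with splicing switches in the epithelial-mesenchymal transition (EMT), epithelial markers, mesenchymal markers, EMT transcription factors, TGF-β pathway and targets, a lung metastasis signature, and invasion, proteases and adhesion. Further lists held interferon-stimulated genes, NF-κB targets and inflammatory cytokines, immediate early genes, cell cycle, p53 targets and apoptosis, replication-dependent histones, unfolded protein and integrated stress response, heat shock, hypoxia and glycolysis, cholesterol and fatty acid synthesis, oxidative phosphorylation, cytosolic ribosomal proteins, noncoding RNAs, luminal breast markers, leukocyte markers, and endothelial and fibroblast markers. The alternatives were pseudocounts of 0.1 and 1, no filter, a mean RPKM of at least 5, median-ratio scaling, quantile normalization, empirical Bayes without a trend and with robust estimation, the replicate number as a block, each library left out in turn, and a minimum fold of 1.5 (limma's treat). A fit that leaves out 1 library assumes that the lone sample of a group varies like the other group. Chosen after seeing the data were protein-coding genes alone, genes with at least 20 estimated reads on average, and median-ratio scaling with the minimum fold or with the replicate number.

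The fit was tested on simulated reads for 12049 genes with the real library sizes and the shared read totals, in which a seeded set of genes was changed. It recovered 33.3% of genes changed 1.5-fold, 97.8% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. It called 146 of 11860 unchanged genes (1.23%), of which 17 had at least 20 reads on average (11115 unchanged genes), so calls on genes with few reads are the less certain ones. With median-ratio scaling the shares were 45.8%, 84.4%, 95.9% and 97.9%, and 19 unchanged genes were called. Only 45 to 49 changed genes were tested per fold, and the spread beyond counting error was set alike for all genes. In the data 36.4% of tested genes were called, which loosens the adjusted threshold, and calls began at log2 fold changes of 0.41 and −0.41. The simulated shares need not hold for the data.

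Reads on overlapping genes cannot be told apart where strand was not used. Of the 120 named genes, 28 share exon positions with another gene in GENCODE 29 and 22 more share only gene body. Values of VIM, CD44, CDH2, ESRP2, ZEB1, MMP1 (with the pseudogene WTAPP1), MAMDC2, DIO2, THBS1, SPARC, KRT7, KRT8 and KRT18 (with each other), HNRNPUL1 (with TGFB1) and IFIT2 (with LIPA) are uncertain to that extent. Keratins, histones, ribosomal proteins and other families with near-identical copies or pseudogenes are uncertain because reads with several matches may have been lost or split. Python 3.11.15 with numpy, scipy and matplotlib was used for the table, the 3′ UTR scan and the plots.

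After these results were seen, 3 further analyses were made. Protein-coding genes were grouped by the letters of their symbols into 240 families with at least 6 tested members, which were tested with camera at the same preset correlation. All 16384 words of 7 bases were counted in the longest annotated 3′ UTR of 9191 genes, among the 400 lowest and the 400 highest log2 fold changes, against the number expected within 20 bins of 3′ UTR length. On simulated changes the scan gave a planted word a z of 16.3, and its highest z was 4.08 where no word was planted. Small RNA genes inside a host gene were compared with the host by Spearman correlation, against 10000 permutations of the hosts, and mitochondrial mRNAs with 10000 sets of nuclear mRNAs drawn from the 100 nearest in RPKM and GC content.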

Results

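The series compared LM2 breast cancer cells after knockdown of hnRNPM, an RNA-binding protein that regulates alternative splicing, with control cells of the same line. Its title concerns hnRNPM, splicing and metastasis in a mesenchymal cell type. Gene-level RPKM values were available for 2 knockdown and 2 control libraries. Between 25668 and 27081 genes had a value above 0 per library, and the estimated reads per library ranged from 16.5 M to 26.6 M. Splicing itself was not measurable from values per gene, so the comparison concerns transcript abundance.

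The targeted gene, HNRNPM (ENSG00000099783), was at 88.6 and 102 RPKM in the control libraries and at 11.5 and 12.95 RPKM in the knockdown libraries. The means were 95.4 ± 9.62 and 12.2 ± 1.04 RPKM (SD, n = 2), a 7.81-fold lower level. The log2 fold change was −2.91 ± 0.17 (SE; limma, adjusted p = 1.48e-59, and 0.000146 with median-ratio scaling). The target was thus low in both libraries labelled knockdown and in neither control library.

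Among the genes that fell most, CSF3, the granulocyte colony-stimulating factor, went from 33.4 ± 2.67 to 2.08 ± 0.0748 RPKM, which is 16.1-fold lower, and MMP1, an interstitial collagenase, from 22.8 ± 2.20 to 1.31 ± 0.109 RPKM, 17.4-fold lower. TGFBR2, the type II TGF-β receptor, was 9.76-fold lower (28.5 ± 3.20 against 2.92 ± 0.241 RPKM), and IL11, a cytokine induced by TGF-β, was 6.28-fold lower (38.4 ± 4.22 against 6.12 ± 0.294 RPKM). LBR, the lamin B receptor of the inner nuclear membrane, was 5.62-fold lower, with a log2 fold change of −2.36. The genes that rose most included CALCR, the calcitonin receptor, from 0.133 ± 0.0125 to 5.77 ± 0.643 RPKM, and CLIC3, an intracellular chloride channel family member, from 0.5301 ± 0.025 to 8.39 ± 0.247 RPKM. MAMDC2 rose from 22.4 ± 1.83 to 151 ± 10.9 RPKM (6.74-fold), the highest level reached among the 12 largest increases.

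The remaining genes with the 12 smallest log2 fold changes were RASD1 (−2.49), PTPRN2 (−2.47), ANP32E (−2.44), MIR135A1 and the unnamed genes ENSG00000221258 and ENSG00000223052. MIR135A1 had 6 and 15 estimated reads in the control libraries and is listed at 0 in both knockdown libraries. The remaining genes with the 12 largest were the myosin light chain gene MYL1 (3.15), the thyroid hormone deiodinase gene DIO2 (3.11), the carboxypeptidase gene CPA4 (2.75), the scavenger receptor gene OLR1 (2.70), PLEKHS1 (2.68), the microRNA genes MIR489 and MIR653, and the unnamed genes ENSG00000238336 and ENSG00000230139. MIR489 and MIR653 lie inside CALCR, had at most 1 read per control library and 10 to 12 per knockdown library, and cannot be told apart from it. MAMDC2 shares exon positions with the antisense gene MAMDC2-AS1.

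In all, 2000 genes were higher and 2964 lower after knockdown among 13627 tested (limma, Benjamini-Hochberg adjusted p under the 0.05 threshold), and 6030 genes had an unadjusted p below it. The smallest log2 fold changes called were 0.41 upward and −0.41 downward. At 2-fold or more, 430 called genes were higher and 608 lower. Higher calls made up 40.3% of all calls, against 50.9% after median-ratio scaling of the libraries, which gave 4235 higher and 4083 lower, moved the median log2 fold change of all genes from −0.07 to 0.00 and kept 4429 of the 4964 calls with 0 in the opposite direction. The counts also moved by over 1.5 times without a filter (262 higher, 255 lower), at a mean RPKM of at least 5 (1047 and 1321) and with a minimum fold of 1.5 (360 and 479), and when a library was left out: 807 higher and 2007 lower without control replicate 1, 1158 and 1057 without control replicate 2, 1029 and 1130 without knockdown replicate 1, and 759 and 1604 without knockdown replicate 2.

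**Figure D1:**
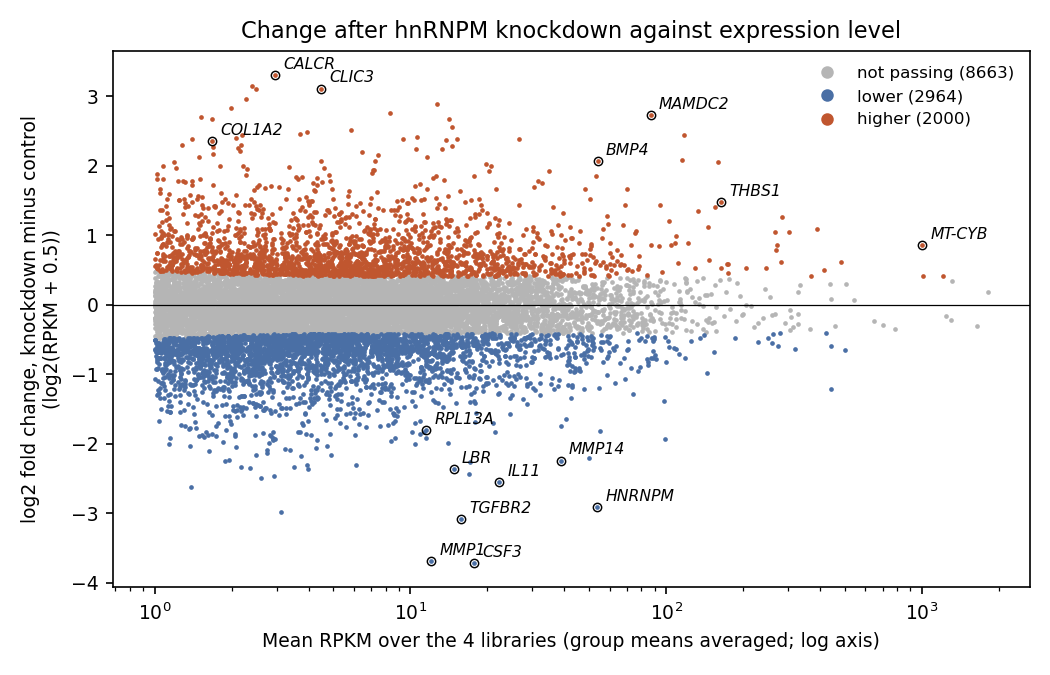
Log2 fold change (knockdown minus control, on log2(RPKM + 0.5)) of each of the 13627 tested genes against its mean RPKM on a log axis, each point being 1 gene from 2 libraries per group. The 2000 genes called higher and the 2964 called lower are coloured, and HNRNPM lies at −2.91, CSF3 at −3.72 and MAMDC2 at 2.73.

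More epithelial and more mesenchymal markers rose than fell. Counts within a list are to be read against the 2000 higher and 2964 lower among all 13627 tested genes. Of 22 epithelial markers tested, 12 rose, 4 fell and 6 did not pass, with a median log2 fold change of 0.46; 53 markers were in the table, and without a filter the median was 0.104. CGN, which codes for the tight junction protein cingulin, rose from 0.415 ± 0.0051 to 3.18 ± 0.443 RPKM, the polarity gene LLGL2 rose 4.29-fold, JUP (plakoglobin, of adherens junctions and desmosomes) 2.86-fold and the simple epithelial keratin KRT7 2.22-fold. MUC1 (1.19), CDH3 (1.10) and ERBB3 (0.73) also rose, each from below 1 RPKM in the control libraries. The 4 that fell were the splicing regulator ESRP2 (−0.935), EHF (−0.795), CLDN7 (−0.648) and SPINT2 (−0.465). EPCAM and KRT19 were among those that did not pass. Of 37 mesenchymal markers tested, 14 rose, 7 fell and 16 did not pass, with a median of 0.28. The type I collagen chain COL1A2 rose 14.9-fold to 3.14 ± 0.2402 RPKM, the gelatinase MMP2 4.21-fold and the matricellular gene THBS1 2.78-fold to 240.4 ± 18.2 RPKM, while MMP14, a membrane-anchored collagenase that activates pro-MMP2, fell 4.88-fold from 64.2 to 13.1 RPKM. Adjusted over the list alone, 12 epithelial markers rose and 4 fell, and 16 mesenchymal markers rose and 7 fell. The epithelial list passed limma's camera test (adjusted p = 0.00182), as did the mesenchymal list (adjusted p = 0.0027). Both calls were lost with an estimated correlation (adjusted p = 0.994 with an estimated correlation for each list), and the epithelial call also at a mean RPKM of at least 5 (adjusted p = 0.0991). The estimated correlation gave that same value for every list, so it does not bear on these lists in particular.

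The cadherins that mark the 2 states were both at very low levels. CDH1 (E-cadherin) had 20 and 16 estimated reads in the control libraries and 131 and 181 in the knockdown libraries, or 0.0701 ± 0.0103 and 0.854 ± 0.193 RPKM. CDH2 (N-cadherin) had 13 and 12 against 136 and 152 reads, or 0.0603 ± 0.00341 and 0.981 ± 0.0771 RPKM. It shares exon positions with an unnamed gene on the opposite strand. Both lay below the expression filter, and without a filter limma gave log2 fold changes of 1.24 ± 0.13 for CDH1 (adjusted p = 0.0552) and 1.40 ± 0.082 for CDH2 (adjusted p = 0.045). In that limma fit no named gene had an adjusted p below 0.0445, which was also the value of HNRNPM. The threshold there thus does not set CDH1 apart from CDH2. Of the mesenchymal markers named beforehand, VIM was at 704 ± 78.8 and 596 ± 48.2 RPKM (log2 fold change −0.24, limma adjusted p = 0.246), FN1 at 50.5 ± 4.46 and 61.4 ± 4.17 RPKM (0.28, adjusted p = 0.196) and CD44, a cell surface receptor whose splicing changes in EMT, at 67.3 ± 6.47 and 53.6 ± 3.56 RPKM (−0.32, adjusted p = 0.129). None of these 3 passed, whereas all 3 passed with median-ratio scaling (adjusted p = 0.00285, 0.000664 and 0.00103).

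Of 24 EMT transcription factors listed, 21 were in the table and 15 were tested. Of these 15, 0 rose, 6 fell and 9 did not pass, against 3 that rose and 9 that fell with median-ratio scaling. The median was −0.26 (−0.153 without control replicate 2 and −0.156 without a filter). Adjusted over the list alone, 0 rose and 6 fell. Among those that fell were FOXQ1 (−1.19), LEF1 (−1.09) and SNAI2, which codes for the repressor Slug (12.3 ± 1.57 against 6.49 ± 0.721 RPKM, −0.87). SNAI2 did not pass without knockdown replicate 1 (adjusted p = 0.0683). ZEB1, a repressor of E-cadherin, was at 5.77 ± 0.613 and 4.37 ± 0.369 RPKM (−0.36, adjusted p = 0.092) and passed only with another scaling or with the replicate number as a block. The list itself did not pass camera (adjusted p = 0.0897).

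**Figure D2:**
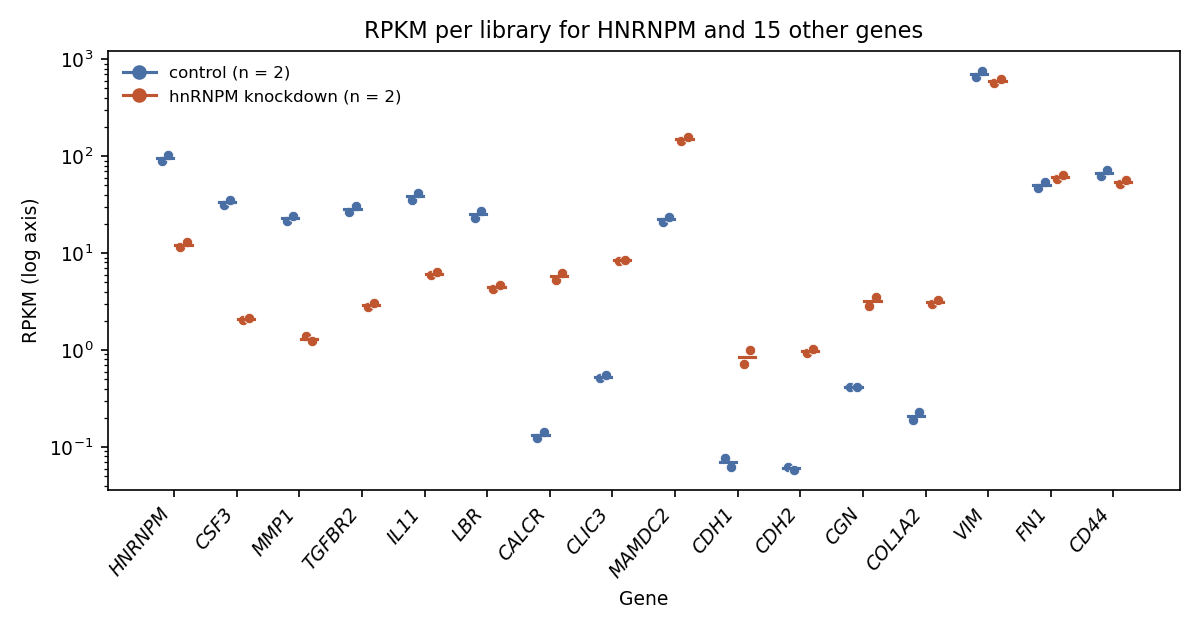
RPKM on a log axis in each of the 4 libraries for HNRNPM and 15 other genes; points are libraries (2 control, 2 knockdown) and bars are group means. HNRNPM lies near 95.4 RPKM in the control and 12.2 RPKM in the knockdown libraries, CDH1 and CDH2 lie below 0.1 RPKM in the control libraries, and VIM, FN1 and CD44 differ by less than 1.5-fold.

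Of 28 tested members of the hnRNP family, to which HNRNPM belongs, 0 rose, 6 fell and 22 did not pass, against 2 that rose and 18 that fell with median-ratio scaling. The share that fell in the main fit was about that of all tested genes, 2964 of 13627. Adjusted over the list alone, 0 rose and 6 fell, and the median was −0.28 (−0.17 without control replicate 2). Besides HNRNPM, the smallest p belonged to HNRNPA3 (−0.56), HNRNPUL1 (−0.52) and HNRNPD (−0.48), each of which failed in all 4 fits that left out 1 library (adjusted p from 0.0567 to 0.456). PTBP1, a repressor of exon inclusion, was at 102 ± 12.1 and 78.6 ± 6.41 RPKM (−0.38, adjusted p = 0.0694; adjusted p = 0.00142 with median-ratio scaling). The family passed camera (adjusted p = 0.045), with an adjusted p = 0.994 with an estimated correlation, and failed without control replicate 2, knockdown replicate 1 or knockdown replicate 2 (adjusted p = 0.0744, 0.158 and 0.152), with empirical Bayes without a trend (0.0634), with protein-coding genes alone (0.0878) and with at least 20 estimated reads (0.0765). Without HNRNPM, the other 27 members had a median of −0.27 and an unadjusted camera p of 0.119.

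Among 37 SR proteins and other splicing regulators, 2 rose, 5 fell and 30 did not pass, against 12 that rose and 17 that fell with median-ratio scaling, and the median was −0.14. It was −0.252 without control replicate 1, −0.0477 without control replicate 2, −0.0762 without knockdown replicate 1 and −0.227 without knockdown replicate 2. Adjusted over the list alone, 2 rose and 4 fell. The muscleblind gene MBNL2 rose from 4.63 ± 0.652 to 16.2 ± 0.414 RPKM (1.71). KHDRBS3, which codes for the STAR protein SLM2, fell 4.01-fold, SRSF4 2.51-fold and the epithelial splicing regulator ESRP2 2.28-fold (2.77 ± 0.248 against 1.21 ± 0.1799 RPKM). Its relative ESRP1 had 3 and 10 estimated reads in the control libraries and is listed at 0 in both knockdown libraries, and limma without a filter gave no call (adjusted p = 0.294). Of 39 genes whose splicing is known to switch in EMT, 5 rose, 8 fell and 26 did not pass (5 rose and 7 fell adjusted over the list alone). Their median was −0.00, their mean was −0.02 and camera pointed up (adjusted p = 0.806); the median was 0.07 with median-ratio scaling, −0.0993 and 0.101 without control replicates 1 and 2, and 0.0577 and −0.069 without knockdown replicates 1 and 2. The syntaxin STX2 fell 2.86-fold and the sugar-phosphate exchanger SLC37A2 1.92-fold, while the cytokine CSF1 rose 2.21-fold and the actin regulator ENAH 2.01-fold. SLC37A2 did not pass without knockdown replicate 1 (adjusted p = 0.0509). The SR protein list did not pass camera (adjusted p = 0.816).

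TGF-β pathway genes changed in both directions. Of 36 tested, 15 rose, 9 fell and 12 did not pass, with the same counts adjusted over the list alone and a median of 0.21 (0.11 without control replicate 1). The type II receptor gene TGFBR2 and IL11 fell, whereas BMP4 rose 4.27-fold to 87.3 ± 5.43 RPKM and FST, which codes for the activin antagonist follistatin, 3.88-fold to 55.3 ± 3.86 RPKM. The BMP target ID3 (1.93) and the activin subunit INHBA (1.503) also rose. The list passed camera upward (adjusted p = 0.0235), with an adjusted p = 0.994 with an estimated correlation and 0.236 at a mean RPKM of at least 5.

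The lung metastasis signature, genes linked in earlier work to lung colonization by MDA-MB-231 derivatives such as LM2, was split. Of 21 tested, 9 rose, 7 fell and 5 did not pass, with the same counts adjusted over the list alone. MMP1 and the chemokine gene CXCL1 (3.41-fold) fell, and MMP2, SPARC (2.55-fold, to 192 ± 12.9 RPKM) and the scaffold gene NEDD9 (1.47) rose. The median was 0.11, the mean was −0.01 and camera gave no call (adjusted p = 0.806); the median was −0.005996 and 0.229 without control replicates 1 and 2, and 0.227 and −0.00426 without knockdown replicates 1 and 2. Of 43 genes of invasion, proteases and adhesion, 10 rose, 16 fell and 17 did not pass (11 rose and 17 fell adjusted over the list alone). MMP1, MMP14 and the integrin gene ITGA2 (2.91-fold) fell, and ICAM1 (3.85-fold) and the sheddase ADAM17 (1.23) rose. Their median was −0.04 and 0.04 with median-ratio scaling, and camera gave no call (adjusted p = 0.671). It was −0.142 and 0.0535 without control replicates 1 and 2, and 0.01975 and −0.108 without knockdown replicates 1 and 2.

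Of 35 interferon-stimulated genes tested, 13 rose, 3 fell and 19 did not pass, with the same counts adjusted over the list alone and a median of 0.22. IFIT1, an antiviral sensor of foreign RNA ends, rose 4.34-fold, IFIT2 3.01-fold, SAMD9 2.89-fold and OASL 2.60-fold. The list passed camera (adjusted p = 0.00182), with an adjusted p = 0.994 with an estimated correlation. NF-κB targets and inflammatory cytokines went both ways: of 24 tested, 9 rose, 5 fell and 10 did not pass (9 rose and 6 fell adjusted over the list alone). The cytokine genes CSF3, IL11 and IL1B (4.24-fold) fell, and ICAM1 rose. The median was 0.31, the mean was −0.08 and camera pointed down without a call (adjusted p = 0.962); the median was 0.046 without a filter and 0.201 without knockdown replicate 2. Of 30 immediate early genes, which respond quickly to growth signals, 6 rose, 13 fell and 11 did not pass, with the same counts adjusted over the list alone and a median of −0.23 (−0.103 without control replicate 2). DUSP4, a MAP kinase phosphatase, fell 2.30-fold and JUN 2.21-fold, while CCN1 rose 2.12-fold to 528 ± 44.1 RPKM and the EGF receptor ligand gene EREG 2.22-fold. That list did not pass camera (adjusted p = 0.338).

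Of 50 cell cycle genes tested, 1 rose (CENPE, 0.77), 26 fell and 23 did not pass, and adjusted over the list alone, 1 rose and 28 fell. The median was −0.46. Those with the smallest p act in DNA synthesis and its control: TK1 (thymidine kinase) fell 1.95-fold from 103 ± 10.8 to 52.6 ± 3.79 RPKM, E2F2 2.69-fold, GINS2 1.99-fold and RRM2, a subunit of ribonucleotide reductase, 1.93-fold. The helicase gene MCM7 (−0.84) and TYMS (−0.83) fell too. The list passed camera (adjusted p = 0.00182), with an adjusted p = 0.994 with an estimated correlation. Of the replication-dependent histones, whose transcripts mostly lack a poly(A) tail, only 5 of 55 could be tested; all 5 rose, also adjusted over the list alone, with a median of 1.26, against 0.197 without a filter. H2BC21 rose 4.87-fold, H2AC6 2.78-fold, H1-2 2.46-fold and H2BC12 2.43-fold. They passed camera (adjusted p = 2.24e-06), with an adjusted p = 0.994 with an estimated correlation. Of 27 p53 targets and apoptosis genes, 11 rose, 5 fell and 11 did not pass, with the same counts adjusted over the list alone and a median of 0.07. It was 0.0395 and 0.175 without control replicates 1 and 2, and 0.137 and 0.0209 without knockdown replicates 1 and 2. The DNA repair gene XPC fell 2.24-fold and FDXR 2.33-fold, and PLK2 rose 1.76-fold and the pro-apoptotic PMAIP1 1.75-fold. PLK2 and PMAIP1 did not pass without control replicate 1 or without knockdown replicate 2 (adjusted p from 0.0504 to 0.0991). The list gave no camera call (adjusted p = 0.292).

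Of 34 genes of the unfolded protein and integrated stress response, 4 rose, 12 fell and 18 did not pass, with the same counts adjusted over the list alone and a median of −0.29 (−0.1798 without control replicate 2 and −0.1703 without knockdown replicate 1). PHGDH and PSAT1, enzymes of serine synthesis, fell 3.22-fold and 2.77-fold, the asparagine synthetase gene ASNS 2.59-fold, and VEGFA 3.27-fold. NUPR1 (−1.20) fell as well. The list did not pass camera (adjusted p = 0.0613) and passed at a mean RPKM of at least 5 (adjusted p = 0.0354). Of 30 cholesterol and fatty acid genes, 10 rose, 5 fell and 15 did not pass, with the same counts adjusted over the list alone and a median of 0.11 (0.00334 and 0.221 without control replicates 1 and 2, and 0.1596 without knockdown replicate 1). The cholesterol exporter gene ABCA1 rose 5.17-fold and the synthase HMGCS1 2.60-fold, while INSIG1, which restrains sterol synthesis, fell 2.59-fold. That list passed camera (adjusted p = 0.0394), with an adjusted p = 0.994 with an estimated correlation, and failed in all 4 fits that left out 1 library (adjusted p from 0.068 to 0.0842) and with median-ratio scaling (adjusted p = 0.103), quantile normalization (0.124), the replicate block (0.0976), no filter (0.0791) or a mean RPKM of at least 5 (0.0991).

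Of 23 heat shock and chaperone genes, 5 rose, 3 fell and 15 did not pass, with the same counts adjusted over the list alone. The co-chaperone DNAJB4 rose 4.82-fold and the small heat shock gene HSPB8 12.6-fold, and BAG3 (−1.29) and DNAJB6 (−1.14) fell. The median was −0.03, the mean 0.11 and the median with median-ratio scaling 0.05, and camera pointed up without a call (adjusted p = 0.306). The median was −0.141 and 0.085 without control replicates 1 and 2, and 0.0208 and −0.105 without knockdown replicates 1 and 2. Of 36 genes of hypoxia and glycolysis, 5 rose, 4 fell and 27 did not pass, with the same counts adjusted over the list alone. VEGFA and ENO2 (1.70-fold) fell, and the glucose transporter gene SLC2A3 (2.66-fold) and the lactate transporter gene SLC16A3 (1.82-fold) rose; GAPDH fell (−0.65), a gene with many pseudogene copies. ENO2 failed without control replicate 2 or either knockdown replicate, and SLC16A3 without knockdown replicate 2 (adjusted p from 0.0575 to 0.123). The median was −0.03, 0.04 with median-ratio scaling, and camera pointed up without a call (adjusted p = 0.962). Without control replicates 1 and 2 it was −0.105 and 0.00874, and without knockdown replicate 2 it was −0.0631.

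Of 46 nuclear-encoded oxidative phosphorylation genes, 3 rose, 3 fell and 40 did not pass, with the same counts adjusted over the list alone. UQCRFS1 (0.63) and NDUFA8 (0.60) rose and ATP5MC1 (−0.52) and NDUFA4 (−0.54) fell; each failed in 3 or 4 of the 4 fits that left out 1 library, with adjusted p up to 0.29. The median was −0.10 (−0.166 and 0.00583 without control replicates 1 and 2, −0.0268 and −0.165 without knockdown replicates 1 and 2), the mean was −0.06, and camera pointed up without a call (adjusted p = 0.967). Of 70 cytosolic ribosomal protein genes, 1 rose (RPL27A, 0.49), 8 fell and 61 did not pass, 0 rose and 5 fell adjusted over the list alone, and the median was −0.17. It was −0.271 and −0.0866 without control replicates 1 and 2, and −0.1096 and −0.262 without knockdown replicates 1 and 2. RPL13A, which hosts small nucleolar RNA genes, fell 3.75-fold from 18.2 ± 1.09 to 4.84 ± 0.432 RPKM, and RPS28 (−0.69), RPL12 (−0.68) and RPL10A (−0.59) fell less and each failed in at least 2 of the fits that left out 1 library (adjusted p up to 0.259). The list gave no camera call (adjusted p = 0.306) but passed downward without a filter (0.02485), with median-ratio scaling (0.0403), quantile normalization (0.0276) or the replicate block (0.01865), and with the last joined to median-ratio scaling (0.0381).

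Of 11 noncoding RNAs tested, 3 rose, 5 fell and 3 did not pass, and adjusted over the list alone, 3 rose and 6 fell, with a median of −0.40 (−0.104 without a filter). NEAT1, the scaffold of paraspeckles, rose 2.55-fold and the nuclear MALAT1 2.18-fold, while the snoRNA hosts DANCR and SNHG5 fell 2.42-fold and 2.07-fold; camera gave no call (adjusted p = 0.659) except at a mean RPKM of at least 5 (adjusted p = 0.0353). Of 9 luminal breast markers, 4 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone and a median of 0.34, against 0.00615 without a filter and 0.198 without control replicate 1. The keratins KRT8 (1.84-fold) and KRT18 (1.85-fold), which share exon positions, and CA12 (1.54-fold) rose and the melanosome transport gene MLPH fell 2.33-fold; camera gave no call (adjusted p = 0.292). CA12 failed in 3 of the 4 fits that left out 1 library (adjusted p up to 0.204), and KRT18 without knockdown replicate 2 (adjusted p = 0.0556). Of leukocyte markers, only 4 could be tested: CD14 rose 4.56-fold, and CD68 (3.35-fold), CD74 (2.57-fold) and LCP1 (2.45-fold) fell. Of endothelial and fibroblast markers, 4 could be tested: COL1A1 (2.56-fold) and COL1A2 rose, and ROBO4 (2.27-fold) and ESAM (1.60-fold) fell. Both lists were too small for a set test, and ESAM failed without control replicate 2 or either knockdown replicate (adjusted p from 0.076 to 0.228).

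Counts in other lists also grew with median-ratio scaling. There 24 mesenchymal markers rose and 12 fell, 21 interferon-stimulated genes rose and 7 fell, 14 NF-κB targets rose and 7 fell, and 3 cell cycle genes rose and 38 fell. Among the splicing switches 17 rose and 11 fell, among invasion genes 21 and 20, and among the stress response genes 12 and 18. Of the heat shock genes 10 rose and 6 fell, of the hypoxia genes 13 and 11, of the cholesterol genes 16 and 9, of the oxidative phosphorylation genes 11 and 12, of the ribosomal protein genes 12 and 30, and of the immediate early genes 10 and 14.

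**Figure D3:**
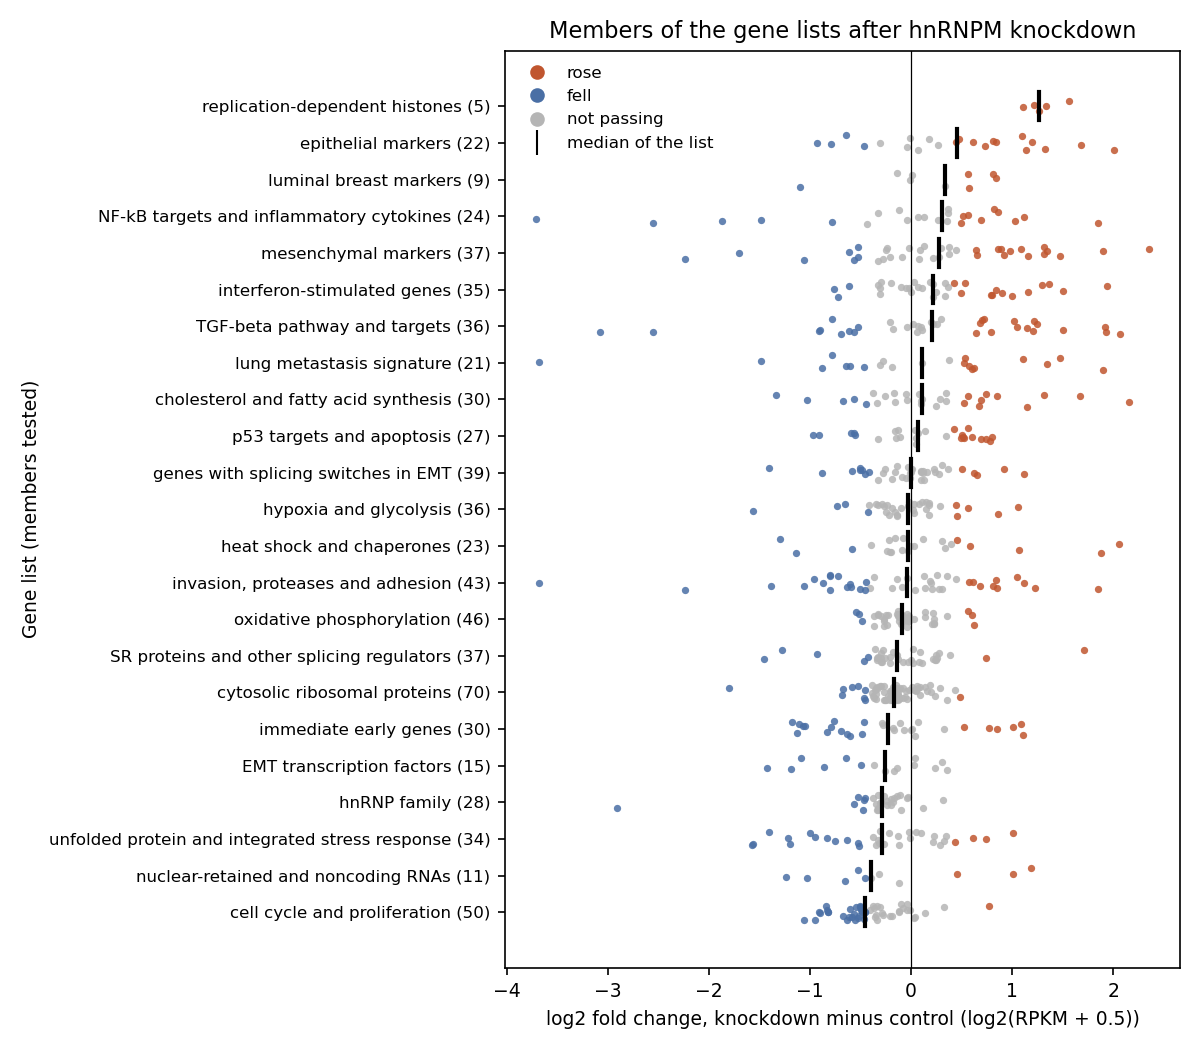
Log2 fold change (knockdown minus control, on log2(RPKM + 0.5)) of the tested members of the 23 lists with at least 5 tested members, 1 point per gene, coloured by whether it rose, fell or did not pass, with a bar at each list's median. Medians run from −0.46 (cell cycle) to 1.26 (replication-dependent histones), and several lists, such as TGF-β and NF-κB, hold strong changes in both directions.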

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

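The tests on protein-coding genes alone, on genes with at least 20 estimated reads, and on median-ratio scaling with the minimum fold or the replicate block were chosen only after the results were seen. HNRNPM kept its direction and its call in every alternative, with log2 fold changes of −3.02 to −2.81 when 1 library was left out. The counts of 2000 higher and 2964 lower genes became 262 and 255 without a filter (31636 genes tested), 1047 and 1321 at a mean RPKM of at least 5 (6792 genes tested) and 360 and 479 with a minimum fold of 1.5. Higher and lower genes numbered 4235 and 4083 with median-ratio scaling, 4091 and 4207 with quantile normalization, and 3109 and 4318 with the replicate block. They numbered 3914 and 3719 with median-ratio scaling and the replicate block, and 645 and 570 with median-ratio scaling and the minimum fold. With 1 library left out they ranged from 759 to 1158 higher and from 1057 to 2007 lower. The epithelial (median 0.46) and mesenchymal (0.28) lists lost their calls with an estimated correlation (adjusted p = 0.994) and with fry's test of a shared direction (adjusted p = 0.408), where 0 lists passed against 8 with limma's camera and 2 had an unadjusted p under 0.05. The estimated correlation gave every list the same adjusted p, so it cannot tell lists apart. Since fry too was run only on values that were not rescaled, a depth difference between libraries may have weakened its calls. fry's test for changes in either direction passed for all 23 lists (epithelial, adjusted p = 0.00336; mesenchymal, 0.0033). That test does not compare members with other genes, and 36.4% of all tested genes were called, so it sets no list apart. The epithelial call was also lost at a mean RPKM of at least 5 (median 0.35). Medians near 0 turned sign with median-ratio scaling, with or without the replicate block: splicing switches 0.0719, invasion 0.03695, heat shock 0.0527 and hypoxia 0.0387. With quantile normalization they did so for splicing switches (0.0429) and hypoxia (0.00644), and VIM went to 0. With 1 library left out, the ranges crossed 0 for splicing switches (−0.0993 to 0.101), lung metastasis (−0.005996 to 0.229), invasion (−0.142 to 0.0535), heat shock (−0.141 to 0.085), hypoxia (−0.105 to 0.00874) and oxidative phosphorylation (−0.166 to 0.00583). The median of all tested genes moved alike, from −0.069 to 0.004 with median-ratio scaling and to 0 with quantile normalization. It was −0.16 and 0.02 without control replicates 1 and 2, and 0.001 and −0.133 without knockdown replicates 1 and 2. The turns of these list medians are thus about the size of a shift shared by all genes. They do not show that the lists themselves are unstable. List medians given above with 1 library left out carry the same shift. Of 1797 comparisons over the other named genes, 1658 kept their direction and side of the threshold, 119 lost a call (68 of them without a filter) and 19 gained one. Of 376 over the other lists, 320 kept both, 29 lost a call, 7 gained one and 20 turned. Depth limits the low genes: in simulated data, 146 of 11860 unchanged genes were called, and 17 of these had at least 20 reads.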

Other observations

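The tests of gene families and of 3′ UTR sites and the scaling comparison for mitochondrial mRNAs were chosen only after the results were seen. The matched sets of nuclear mRNAs and the comparison of small RNA genes with their hosts also came after the results above. Of 12 collagen genes tested, 9 rose, 2 fell and 1 did not pass, with a median log2 fold change of 0.87. The fibrillar chains COL1A2 (2.36), COL1A1 (1.32) and COL5A1 (1.31) and the basement membrane chain COL4A5 (1.40) rose, while COL6A3 (−1.70) and COL13A1 (−0.96) fell. The family was 1 of 2 among 240 that passed limma's camera (adjusted p = 0.00222; adjusted p = 0.999 with an estimated correlation).

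The mitochondrially encoded mRNAs were the other family. Of 13 tested, 10 rose, 0 fell and 3 did not pass, with a median of 0.61 (limma's camera, adjusted p = 0.00222; adjusted p = 0.999 with an estimated correlation). MT-CYB went from 713 ± 67.4 to 1290 ± 80.2 RPKM (SD, n = 2; 0.86) and MT-CO2 from 73.2 ± 4.94 to 145.5 ± 4.18 RPKM (0.99). Of the mitochondrial rRNAs, MT-RNR2 rose (0.41) and MT-RNR1 was at −0.09 (adjusted p = 0.711). Of 22 mitochondrial tRNA genes, 15 rose and 2 fell, MT-TF (−1.93) and MT-TT (−1.21), but these are not 22 separate measurements: MT-TC and MT-TY have identical values, so reads appear to be counted on more than 1 of them.

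The prediction for scaling of the libraries was that median-ratio scaling would bring these 13 mRNAs to the median of all genes. They stood 0.69 above it. However, median-ratio scaling divides each library by 1 factor and moves all genes almost alike. In the main fit their median was 0.61 against −0.07 for all genes, and that distance could hardly change. The comparison was thus fixed in advance and does not test scaling. A trend with expression level and GC content would move nuclear mRNAs alike. Sets matched on both had a median of −0.0022, and a share of 0.0007 of them reached the median of the 13 mRNAs (95th percentile of the sets, 0.285). Their genes were drawn 1 by 1, so that share does not allow for mRNAs that move together. How close the nearest genes lie at the highest RPKM was not checked, so such a trend is not excluded. Reads shared with nuclear copies of mitochondrial DNA were not tested, and MT-CO1 (4.09 ± 0.372 RPKM in control libraries, SD, n = 2) and MT-ND2 (5.59 ± 0.745 RPKM) had low values. A higher level of mitochondrial transcripts after loss of hnRNPM may account for the pattern and was not tested.

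Among the 400 genes lowest after knockdown, 75 held 3′ UTR sites matching CATAGGA where 35.2 were expected (z = 7.56), and 107 held the overlapping ATAGGAA where 58.5 were expected (z = 7.66); TGFBR2, LBR, SRSF4 and SNAI2 hold the joined CATAGGAA, and CSF3, MMP1, IL11 and MMP14 hold none of these. Unrelated GC-rich words followed closely: GCTGGCC (z = 6.56), CGCCGGG (6.30) and AGCCCCG (6.198). The median log2 fold change was −0.26 for genes with CATAGGAA, −0.13 with CATAGGA outside it, and −0.06 both with ATAGGAA alone and with none of these. These words were picked from the same genes, so the medians are no separate test of them. Outside the odd-numbered chromosomes, the median of the 146 genes with CATAGGAA differed by −0.15 from that of genes with none of these.

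Base composition and length of 3′ UTRs would raise other orders of the same bases too, yet ATAGGAA, picked on odd-numbered chromosomes, had a z of 5.72 on the others, 2.73 above the highest of the other orders of its bases within length bins. Pairing of the silencing RNA's seed with 3′ UTRs may contribute, since there the genes with ATAGGAA differed by a median of −0.0356 (630 genes, permutation p = 0.0001, the smallest possible; permuted values had a median of 0.0447 and a lowest of −0.0285). These 630 genes include those with CATAGGAA, and over all chromosomes genes with ATAGGAA alone lay no lower than genes with none of these words. The pick of ATAGGAA followed an adjustment for composition added after the first pick, CGCCGGG, had failed (−0.07, 43 genes, permutation p = 0.103). The target itself argues weakly: 5 of 11 HNRNPM transcripts hold CATAGGA upstream of the 3′ UTR, and 12.1% of all 7-base words occur in the longest. An endogenous microRNA with the same seed cannot be told apart from it, because the host gene of miR-202 had 0 reads in all 4 libraries and mature microRNAs were not measured, and loss of hnRNPM itself stays open, untested.

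Small RNA genes that lie inside a host gene moved with the host, as MIR489 and MIR653 did with CALCR. Joint transcription of the host and the small RNA as the whole cause would leave small RNA genes on the opposite strand without a correlation, and for these the permutation p was 0.0001, the smallest possible. Only the host with the highest mean RPKM was kept, so a gene classed as opposite-strand may also lie inside a same-strand gene. The test therefore cannot exclude joint transcription. Reads of the host transcript counted on the small RNA gene may account for the shared movement, since rho was 0.668 across 402 opposite-strand genes and 0.671 across 710 same-strand genes. Loss of hnRNPM stays open as a cause for single small RNA genes and was not tested.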
